A study of Mus musculus with 11 samples.

How the data were processed

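The samples were cells of fetal livers taken from C57/Bl6 mouse embryos at embryonic day 14.5. Per the labels' protocols, the freshly isolated livers were stained with antibodies against Ter119, an antigen of erythroid cells, and CD71, the transferrin receptor. The cells were sorted by flow cytometry into successive stages of erythroid development, named R1 to R5. Total RNA of each sorted fraction was hybridised to 1 array. The labels name Cy5 as the single dye, while the probe set identifiers and the annotation table are those of a mouse short-oligonucleotide expression array, and which labelling step applied to that array is not settled by the sources used here. The series holds 11 arrays, with 2 of R1, 3 of R2, 3 of R3, 1 of R4 and 2 of R5. Nothing in the labels says whether the arrays of a stage came from separate litters or sorts, so p-values measure only the spread between these arrays, which may be technical.

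The authors deposited 1 signal intensity per probe set and array, on a linear scale, for 45101 probe sets, of which 64 are controls. The submitters' processing notes name MAS5 and limma, with no version given. On each array the mean of the deposited intensity, after trimming 2% of the probe sets at each end, was 500, which is the form of scaling MAS5 applies. No detection calls or scan information were used, and the number of arrays limits the precision. A second table that the authors deposited holds, for 45037 probe sets, mean log2 signals per stage, log2 differences of each stage from R2 (headed as ratios) and p-values. Its means equalled the means of log2 intensity within 0.005. Its p-values per stage matched Benjamini-Hochberg adjusted p-values from limma's default settings within 0.001, as recomputed here from the deposited intensities. Its F-test p-values matched unadjusted ones within 0.0001.

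Intensities were transformed to log2 with no pseudocount, since all values were positive, and with no further normalization. Probe sets were named through the platform annotation, whose symbols were compared with current ones by gene identifier and needed no update. Of the probe sets other than controls, 34945 had 1 gene, 932 had several and 9160 had none listed. Probe sets with several genes were not named and not tested. For each of the 18194 genes, the probe set with the highest mean over all 11 arrays was used. Genes were tested where this probe set lay at or above the array's median on at least 2 arrays, which left 13100 genes. Of the tested genes, 67 had no match by gene identifier and kept the annotation's symbol.

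All 11 arrays entered 1 limma fit (lmFit, then eBayes with an intensity trend; limma 3.58.1 in R 4.3.3) with a mean per stage, 6 residual degrees of freedom and 4.83 prior degrees of freedom. Each comparison was tested per gene with Benjamini-Hochberg adjustment over the 13100 genes, and a gene was called at an adjusted p under 0.05. Log2 changes are on the deposited scale, beside the median change of all genes in each comparison, and are given with the standard error (SE) of that fit, and levels with the SD over arrays. The single R4 array is assumed to vary like those of the other stages. The fit pools the spread of R1, R2, R3 and R5, so arrays outside a comparison also affect it.

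Of the 26 gene lists fixed in advance, 19 were pathways or gene families and 7 were markers of other cell types of the fetal liver. Each was tested in 4 comparisons with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 104 tests. Camera compares the members with all other genes. With the preset correlation 59 tests passed an adjusted p of 0.05. With a correlation estimated from the arrays 0 passed, and the smallest adjusted p was 0.29. With fry, which asks whether the members move one way on balance, 31 passed. Counts of called members are given over all genes tested and adjusted over the list alone.

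The design, the lists, the rule for named genes and the alternatives, except for the block on the arrays numbered 1 and 2, were fixed before the data were examined. For R2 against R1, R3 against R2 and R5 against R3, the rule takes the 10 largest rises and 10 largest falls among called genes whose arrays do not overlap, leaving out unnamed transcripts. For the other comparisons it takes 5 each way. From each list it takes up to 4 members with the largest change and any that passed the test in the other direction. Tfrc, which encodes CD71, and Hipk2 were to be reported in every case, and a further gene that the rule names is not reported here. A gene named outside this rule is said to be so. Where a gene had several probe sets, they could differ: of the 1405 genes called between R3 and R2 with over 1 tested probe set, 191 had a probe set of opposite sign.

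Per the labels, RNA extraction shared a date within a set of replicates, without saying what a set is. Read as arrays of 1 number across stages, this makes the number an extraction date. Read as the arrays of 1 stage, it leaves date and stage impossible to tell apart. The first reading was checked in a way chosen after the result was seen, on the difference between the arrays numbered 1 and 2 of each stage, since deviations from the mean of 2 arrays are mirror images. The differences of R1, R2, R3 and R5 correlated at 0.15 to 0.37 in all 6 pairs of stages, and of the 8 ways to number these arrays 1, the real one, gave a sum as high, which is the smallest share 8 ways can give. The difference of the array numbered 3 from the others correlated at -0.15 between R2 and R3. These correlations are across genes, which are not independent replicates. Which reading holds is not settled. The block uses the first, and values with it as a block are given where they change a reported call or move a reported count by over 1.5 times.

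The fitting code was tested on simulated arrays with the measured means and spreads, 13100 genes and 67, 67 and 66 genes changed by 1, 2 and 4 on the log2 scale. Noise was drawn independently for each gene and array, with no variation shared by the genes of an array or by replicate number. The shares recovered therefore check the code and do not give the power on the real arrays. For R3 against R2 it recovered 46.3% of genes changed by 2 on the log2 scale and 84.8% of those changed by 4. For R2 against R1 the shares were 49.3% and 63.6%, for R5 against R3 they were 23.9% and 80.3%, and for R5 against R1 they were 31.3% and 68.2%. Alternatives tried were quantile normalization, median centring, other filters on dim probe sets, a floor on low values, default and robust eBayes, fits of only the stages compared, the replicate block, other treatment of probe sets, other thresholds, array weights and leaving out each array in turn. Leaving out an array of R1 or R5 leaves 1 array of that stage, which is then assumed to vary like those of the other stages. Counts from such fits have no replicate check for that stage. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.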

Results

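Gene expression was measured by array in mouse fetal liver cells, sorted by the surface markers Ter119 and CD71 into the stages R1 to R5, which the labels describe as successive. In the sorting scheme the labels cite, R1 holds the least mature cells and R5 the most mature. There were 2 arrays of R1, 3 of R2, 3 of R3, 1 of R4 and 2 of R5, with 13100 genes tested. The question of the series is how expression changes through terminal erythroid differentiation. Of these genes, 4839 differed between R1, R2, R3 and R5 (limma moderated F-test, Benjamini-Hochberg adjusted p under 0.05), and 6950 had an unadjusted p under 0.05. Without replicate 1 of R1 the count was 3082, without replicate 2 of R1 it was 2769, without replicate 1 of R2 it was 2695 and without replicate 1 of R3 it was 3124.

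Arrays of a stage correlated at r = 0.85 to 0.95 across genes, which are not independent replicates, and no arrays held identical values. The first principal component held 48.4% of the variance and placed the 5 arrays of R1 and R2 between -104.79 and -46.90 and the 6 arrays of R3, R4 and R5 between 35.68 and 123.38. The second held 17.9% and placed the R5 arrays at 62.53 and 49.47 and the R3 arrays at -36.10, -43.70 and -38.10. Signal was more concentrated at later stages. The 100 brightest probe sets took 8.81% and 8.32% of the signal on the R1 arrays, and 15.6% and 16.9% on the R5 arrays. Median signal was 62.5 and 92.1 in R1 and 120.4 and 107.6 in R5. The 3' minus 5' log2 signal of the pyruvate carboxylase control, a sign of RNA length, was 0.20 and 0.38 in R1, 0.75 to 1.84 in R2, 2.45 to 3.29 in R3, 2.72 in R4 and 4.62 and 2.27 in R5. For the beta-actin control it lay between 0.21 and 0.83 on all 11 arrays. For the Gapdh control it was 0.23 and 0.20 on the R5 arrays and between -0.46 and -0.01 on the other 9, and for the transferrin receptor control it lay between 1.63 and 3.37.

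**Figure D1:**
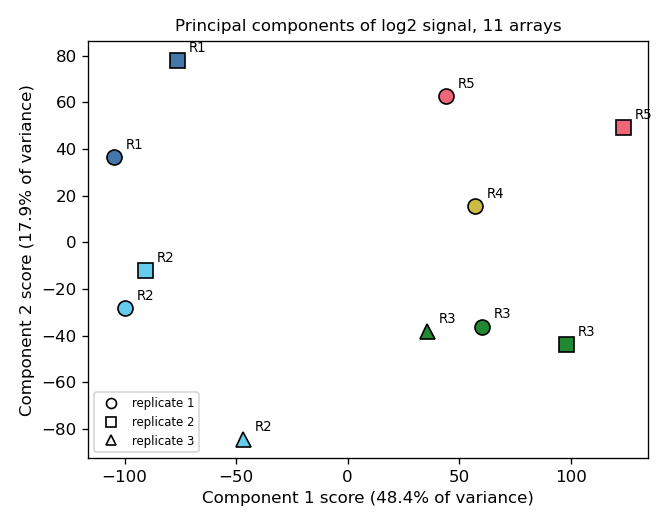
Scores of the 11 arrays on the first and second principal components of log2 signal over 13100 genes, coloured by stage and shaped by replicate number. The R1 and R2 arrays lie below -46.90 on the first component and the R3, R4 and R5 arrays above 35.68.

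R2 was compared with R1 to ask what changes at the first step. Red cell membrane and skeleton genes were higher in R2: of 17 measured, 5 rose and none fell over all genes tested, 13 rose adjusted over the list alone, and all 17 changes were positive. Add2, a subunit of the skeletal protein adducin, rose by 2.73 ± 0.42 on the log2 scale (SE; 3 R2 and 2 R1 arrays), the blood group gene Rhd by 2.70 ± 0.43 and Icam4 by 2.41 ± 0.38. The rises included Epor, the erythropoietin receptor (2.45 ± 0.34), Klf1, an erythroid transcription factor (2.33 ± 0.38), Alad, an enzyme of heme synthesis (2.11 ± 0.33), Tfr2 (1.79 ± 0.30), the red cell pyruvate kinase Pklr (2.71 ± 0.37) and the reductase Blvrb (2.30 ± 0.32). Of 7 heme synthesis genes 1 rose, or 6 adjusted over the list alone. Osm, a cytokine gene in the erythropoietin signalling list, changed by -2.76 ± 0.41. In each of these genes the limma adjusted p lay between 0.0335 and 0.0414. Tfrc, which encodes the sorting marker CD71, differed by 1.51 ± 0.36 and Hipk2, a kinase gene, by 0.24 ± 0.40 (limma adjusted p = 0.109 and 0.861). Of 7 tested Hipk2 probe sets 2 had the opposite sign. The median of the membrane list was 1.98, or 2.03 relative to the median of all genes, and that of the heme list 1.52, or 1.57 relative to it. The camera adjusted p was 8.19e-17 and 9.69e-09, and for both lists the adjusted p = 0.29 with an estimated correlation. All 26 DNA replication genes and all 30 ribosome biogenesis genes had positive changes, with medians of 0.49 and 0.62, and 0 were called in either list over all genes or adjusted over the list alone. Camera gave them adjusted p of 9.12e-08 and 1.81e-05, and the adjusted p was 0.41 and 0.58 with an estimated correlation. Without replicate 2 of R1 the camera adjusted p of the ribosome biogenesis list was 0.0718.

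The largest rises from R1 to R2 were in the neuropeptide gene Tac2 (5.43 ± 0.79), Mrap (4.33 ± 0.80), Myh7b (3.68 ± 0.62), Spon2 (3.42 ± 0.59) and the sphingosine kinase gene Sphk1 (3.32 ± 0.51). Tlcd4, the connexin gene Gjb2, Pdia2, the nuclear lamina gene Lmna and the water channel gene Aqp3 followed, with rises from 3.29 to 3.00. Tac2, Mrap, Myh7b, Spon2, Gjb2 and Aqp3 lay below the array median in R1, so the size of their change is less certain. The R1 arrays differed in Mrap and Myh7b, with SDs of 2.03 and 1.68, and over arrays left out in turn their changes ranged from 2.90 to 5.76 and from 2.49 to 4.87. Among the largest falls, the granzyme gene Gzma changed by -6.48 ± 1.00, the neutrophil collagenase gene Mmp8 by -5.85 ± 0.96, Plbd1 by -4.38 ± 0.75 and Ctla2a by -4.08 ± 0.67. Thbs1, a gene of the megakaryocyte list, changed by -3.80 ± 0.69, and Clec4e, Gimap4, S100a4, Gimap8 and Slfn8 by between -3.77 and -3.19. The R1 arrays differed in some of these: the SD of log2 signal was 2.47 for Gzma, 2.37 for Mmp8 and 2.30 for Plbd1. Over arrays left out in turn these 3 changes ranged from -8.22 to -4.73, from -7.53 to -4.18 and from -6.01 to -2.76. Gzma, Clec4e, Gimap8 and Slfn8 lay below the array median in R2, so the size of their change is less certain too.

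Markers of other cell types moved with this step. The medians of the mast cell, lymphocyte, macrophage, hepatocyte and endothelial lists were -2.52, -2.02, -1.53, -1.17 and -0.89, with camera adjusted p from 2.83e-05 to 0.00209. In the haematopoietic progenitor list, 17 of 19 changes were negative and the median was -1.82, or -1.77 relative to the median of all genes (camera adjusted p = 1.05e-06), with 0 members called over all genes and 10 lower adjusted over the list alone. Replicate 3 of R2 was lowest, with a mean of 8.26 in the progenitor list against 9.69 and 9.81 on the other R2 arrays. In the lymphocyte list it was at 7.05 against 9.02 and 9.88, so of the R2 arrays it carried the most of both falls. The R1 arrays were at 9.12 and 12.04 in the lymphocyte list, so the fall of that list also depended on replicate 2 of R1. The camera calls of these 6 lists were lost with an estimated correlation, with adjusted p between 0.29 and 0.51. In the first 5 lists 0 members were called over all genes, and 4 mast cell, 2 lymphocyte, 6 macrophage, 0 hepatocyte and 2 endothelial members were lower adjusted over the list alone. Without replicate 2 of R1 the camera adjusted p was 0.39 for the lymphocyte and 0.107 for the macrophage list. In the granulocyte list 6 of 13 changes were positive, the median was -0.30 and 0 members were called over all genes or adjusted over the list alone (camera adjusted p = 0.275). In the megakaryocyte list the median was -0.61, with 1 member lower over all genes and 2 adjusted over the list alone (camera adjusted p = 0.0281; adjusted p = 0.52 with an estimated correlation). That list had a camera adjusted p of 0.105 after quantile normalization, 0.322 without replicate 1 of R1 and 0.387 without replicate 2 of R2.

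In all, 61 genes were called between R2 and R1 (limma, adjusted p under 0.05), 46 higher and 15 lower in R2, and 1750 had an unadjusted p under 0.05. In all 61 the arrays of the stages did not overlap, which held for 36.3% of all genes, where chance gives 20%. The median change of all genes was -0.05, or 0.24 with each array centred on its median. The share higher was 75.4%, and 87.5% after quantile normalization. With the replicate number as a block 0 genes were called and 1704 had an unadjusted p under 0.05, and the limma adjusted p of each of the 30 called genes covered by the rule for named genes then lay between 0.0597 and 0.0799. With only the arrays numbered 1 and 2 and the block, a setting chosen after seeing the data, 90 genes were called, 48 higher and 42 lower. The count was also 0 with default eBayes and with a fit of only these stages, and it was 0 without replicate 2 of R1, without replicate 2 or 3 of R2 or without any 1 of the 3 R3 arrays, 15 without replicate 1 of R1 and 11 without replicate 1 of R2.

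R3 was compared with R2 to ask what changes as cells gain Ter119. Genes for hemoglobin and its heme were higher in R3. All 7 measured heme synthesis genes rose, among them Alas2, the first enzyme of the pathway in erythroid cells, by 5.48 ± 1.15 (SE; 3 arrays of each stage), Fech by 2.75 ± 0.33, Ppox by 2.67 ± 0.40 and Uros by 2.53 ± 0.36. Of 6 measured globin-list genes 5 rose. These included the embryonic globins Hbb-bh1 (6.09 ± 0.59), Hba-x (4.34 ± 1.28) and Hbb-y (2.79 ± 0.85), and Hbb-b2 (5.80 ± 1.03), for which another probe set had the opposite sign. On the arrays numbered 2, however, Hba-x was at 9.41 in R2 and 9.53 in R3 and Hbb-y at 12.57 and 12.13, so the rises of both came from the other arrays. Which cells of a sorted fraction held the embryonic globin transcripts was not tested, so these rises need not be changes within 1 cell type. The limma adjusted p of Hba-x lay between 0.0559 and 0.125 without any 1 of the R2 arrays or replicate 1 or 3 of R3, and that of Hbb-y between 0.055 and 0.146 without those or either R1 array. The main adult alpha- and beta-globin probe sets match several genes and were not tested. The 3 probe sets that match both adult alpha-globin genes had log2 signals of 14.83 ± 0.35, 14.84 ± 0.32 and 13.49 ± 1.31 (SD, n = 3) in R2 and of 15.75 ± 0.28, 15.55 ± 0.30 and 15.75 ± 0.12 (SD, n = 3) in R3. A probe set that matches adult beta-globin genes, Hbb-b2 among them, was at 14.71 ± 0.44 in R2 and 15.24 ± 0.24 in R3. The median changes of the heme and globin lists were 2.53 and 3.57, or 2.67 and 3.71 relative to the median of all genes, and 7 heme and 5 globin-list genes rose adjusted over the list alone. In camera the adjusted p was 2.86e-06 for heme and 0.000189 for globins, and for both lists the adjusted p = 0.29 with an estimated correlation. Ppox had another probe set of opposite sign.

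Of 17 red cell membrane and skeleton genes 15 rose and none fell. The dematin gene Dmtn rose by 4.42 ± 0.48, the anion exchanger gene Slc4a1 (band 3) by 4.23 ± 1.04, Epb42 by 3.87 ± 0.86 and Tmod1 by 3.35 ± 0.67. Of 15 iron genes 7 rose, led by the mitochondrial iron importer Slc25a37 (3.61 ± 0.60) with Abcb10 (2.21 ± 0.45) and Slc25a38 (1.55 ± 0.35), while the heme exporter gene Flvcr1 and Aco1, which encodes an iron-regulated RNA-binding protein, fell by 2.31 ± 0.43 and 1.42 ± 0.31. Tfrc, which encodes the sorting marker CD71, rose by 1.49 ± 0.32. Among 20 erythroid transcription factors 12 rose, including Sox6 (4.66 ± 0.61), E2f2 (3.73 ± 0.50), Foxo3 (3.16 ± 0.27) and Nfe2 (3.00 ± 0.31), and 2 fell, Tcf3 by 1.94 ± 0.29 and Ldb1 by 1.27 ± 0.32. Of the 3 measured HIPK kinase genes, Hipk2 rose by 2.54 ± 0.35 and Hipk1 by 2.16 ± 0.33 (limma adjusted p = 0.00163 and 0.00261). The change of Hipk3 was 0.81 ± 0.36, with a limma adjusted p of 0.114, or 0.0155 with the replicate block. Without replicate 1 of R2 the limma adjusted p of Tfrc was 0.0614, that of Slc4a1 0.0618, that of Epb42 0.0508 and that of Slc25a38 0.0624. For Slc4a1 the limma adjusted p was also 0.0524 and 0.064 without replicate 1 or 2 of R3, for Epb42 0.0586 without replicate 2 of R3, and for Slc25a38 0.0585 and 0.0592 without replicate 2 of R2 or of R3. Aco1 had 0.0599 and 0.0511 without replicate 2 of R2 or 1 of R3, and Ldb1 had from 0.0514 to 0.0951 without replicate 1 or 2 of R2 or 2 or 3 of R3. Adjusted over the list alone, 16 membrane genes rose, 8 iron genes rose and 2 fell, 12 erythroid factors rose and 3 fell, and 3 HIPK genes rose. Camera gave an adjusted p of 6.87e-11 for membrane, 0.00405 for iron, 2.35e-05 for erythroid factors and 0.00448 for HIPK genes. In the same order the adjusted p was 0.30, 0.52, 0.29 and 0.40 with an estimated correlation. Flvcr1 had another probe set of opposite sign.

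**Figure D2:**
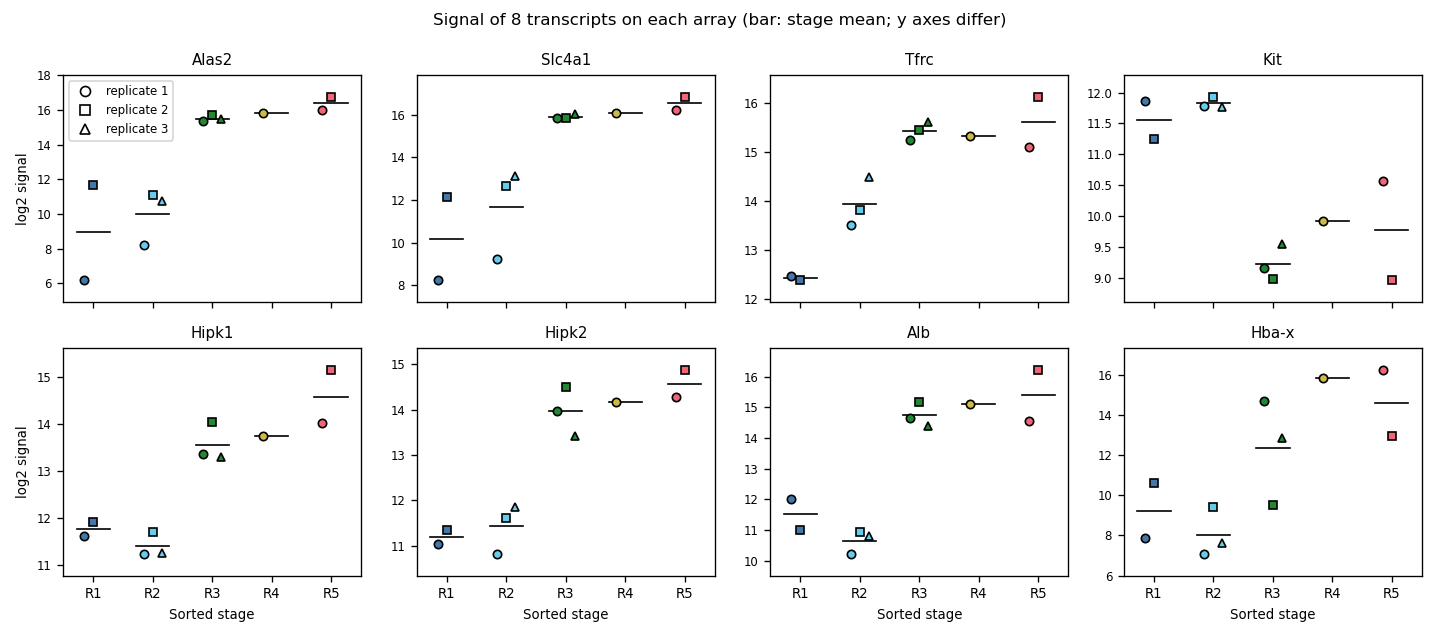
Log2 signal of 8 transcripts on each of the 11 arrays by sorted stage, with symbols for the replicate number and a bar at the stage mean; the y axes differ. Alas2 has stage means of 8.93, 10.02, 15.50, 15.80 and 16.38 from R1 to R5, and Kit has means of 11.83 in R2 and 9.23 in R3.

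Part of the genes of cell division and of its brakes rose from R2 to R3. Of 26 mitosis genes 14 rose, including Ube2c (2.25 ± 0.28), Prc1 (1.58 ± 0.38), the proliferation marker Mki67 (1.54 ± 0.24) and Tpx2 (1.47 ± 0.25), and of 26 DNA replication genes 4 rose, including Rrm2 (1.65 ± 0.27) and Pcna (0.93 ± 0.27). Of 17 cell cycle brakes 10 rose, led by the Myc antagonist Mxd1 (4.25 ± 0.61), the cyclin-dependent kinase inhibitor Cdkn2d (3.64 ± 0.48), Btg2 (3.27 ± 0.40) and Gadd45a (3.12 ± 0.44). In that list 3 fell, Ccng1 by 1.77 ± 0.48, Mxd4 by 1.48 ± 0.44 and Rbl2 by 1.12 ± 0.35. Of 30 ribosome biogenesis genes 19 fell and none rose, with all 30 changes negative and a median of -1.85, or -1.71 relative to the median of all genes: Rrp9 fell by 3.26 ± 0.74, Pes1 by 2.94 ± 0.47, Polr1b by 2.49 ± 0.59 and Nop58 by 2.32 ± 0.40. Of 19 progenitor genes 5 fell, including the stem cell factor receptor gene Kit by 2.60 ± 0.39, Myc by 2.24 ± 0.48 and Myb by 2.21 ± 0.49. Adjusted over the list alone, 17 mitosis and 4 DNA replication genes rose, 10 brakes rose and 3 fell, 24 ribosome biogenesis genes fell and 6 progenitor genes fell. The camera adjusted p was 6.41e-09 for mitosis, 0.0324 for DNA replication, 0.000191 for brakes, 1.47e-08 for ribosome biogenesis and 0.00625 for progenitor genes. In the same order the adjusted p was 0.41, 0.71, 0.41, 0.52 and 0.61 with an estimated correlation. The DNA replication list lost its call after quantile normalization (camera adjusted p = 0.235), without the filter on dim probe sets (0.0827), without replicate 1 or 2 of R2 (0.119 or 0.0689) and without replicate 3 of R3 (0.175). With 1 array left out, Pcna lost its call without either R1 array, replicate 1 or 2 of R2 or any R3 array (limma adjusted p from 0.0501 to 0.119). So did Rbl2 without any array of R1 or R2 or replicate 1 or 2 of R3 (0.0539 to 0.145), Mxd4 without either R1 array or replicate 1 or 2 of R2 or R3 (0.0548 to 0.13) and Ccng1 without any R2 array or replicate 1 or 2 of R3 (0.0565 to 0.0994). Prc1 and Polr1b did without replicate 1 or 2 of R2 or 2 of R3 (limma adjusted p up to 0.0731), Rrp9 and Myb without replicate 1 of R2 or 2 of R3, and Myc without replicate 2 of R3. Tpx2 had another probe set of opposite sign.

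Many genes of protein and organelle turnover were higher in R3. Of 19 ubiquitin enzymes 12 rose, led by Ube2l6 (4.46 ± 0.71), Trim10 (4.37 ± 0.77), Rnf11 (4.08 ± 0.29) and Ube2o (4.03 ± 0.51). Of 24 autophagy genes 12 rose, led by the proteases Atg4a (3.37 ± 0.44) and Atg4d (2.89 ± 0.35), with Gabarapl2 (2.77 ± 0.33) and Ulk1 (2.68 ± 0.34), and 2 fell, Atg3 by 1.93 ± 0.38 and Atg5 by 1.55 ± 0.35. Of 15 antioxidant genes 8 rose, including Nqo1 (1.67 ± 0.33), Gclm (1.63 ± 0.33) and Blvrb (1.61 ± 0.28). The erythropoietin signalling list went both ways: 6 of 19 rose, including Socs3 (4.06 ± 0.54), the survival gene Bcl2l1 (3.10 ± 0.40), Pim1 (2.79 ± 0.42) and Cish (2.78 ± 0.29), and 4 fell, Ptpn6, Stat5a, Stat5b and Nr3c1, by 2.17, 2.13, 1.88 and 1.23. In the glycolysis list the glucose transporter gene Slc2a1 rose by 4.33 ± 0.29 and Bpgm, whose product makes the hemoglobin ligand bisphosphoglycerate, by 3.85 ± 0.50, while Pgd fell by 3.22 ± 0.58 and Aldoa by 1.81 ± 0.54. Of 24 chromatin and enucleation genes 5 rose, led by Xpo7 (4.71 ± 0.44), and 3 fell, Kat2a by 2.66 ± 0.55, Dnmt3b by 2.34 ± 0.67 and Lmnb2 by 1.94 ± 0.42. Of 26 oxidative phosphorylation genes 2 rose, Cox6c by 0.71 ± 0.23 among them, and Sdhd fell by 1.41 ± 0.36. Of 15 apoptosis genes, Bcl2l1 rose and Bid fell by 2.39 ± 0.51. Under the replicate block 5 oxidative phosphorylation genes were higher and 3 lower, 3 glycolysis genes higher and 6 lower, 3 apoptosis genes higher and 2 lower, 5 chromatin and enucleation genes lower and 1 ubiquitin enzyme lower. With 1 array left out, Cox6c lost its call without any array of R1, R2 or R3 (limma adjusted p from 0.0583 to 0.156), and Dnmt3b without any of these but replicate 3 of R3 (0.0503 to 0.133). Sdhd and Ptpn6 did without replicate 1 or 2 of R2 or 2 of R3 (up to 0.0939), Stat5a without these or replicate 3 of R3 (up to 0.132), and Aldoa without any array of R1 or R2 or replicate 2 of R3 (0.0503 to 0.138). So did Nr3c1 without replicate 2 or 3 of R2 or 1 or 2 of R3 (up to 0.0799), Atg5 and Lmnb2 without replicate 1 of R2 or 2 of R3 (up to 0.0618), Stat5b without replicate 2 of R3 (0.0551) and Bid without replicate 1 of R2 (0.0509). Nr3c1 and Aldoa had another probe set of opposite sign.

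Adjusted over the list alone, 14 ubiquitin enzymes rose and 1 fell, 14 autophagy genes rose and 5 fell, and 9 antioxidant genes rose. In camera these lists had adjusted p of 5.71e-09, 0.000678 and 0.00025, and for each of them the adjusted p = 0.29 with an estimated correlation. Adjusted over the list alone, 7 erythropoietin signalling genes rose and 7 fell, 3 glycolysis genes rose and 5 fell, 5 chromatin and enucleation genes rose and 5 fell, and 1 apoptosis gene rose and 1 fell. No oxidative phosphorylation gene passed in that way. These lists were not called, with camera adjusted p of 0.261, 0.619, 0.734, 0.526 and 0.611. Oxidative phosphorylation was placed upward by camera although its median and mean were -0.00 and -0.01, with the median of all genes at -0.14. The limma adjusted p of the genes named as called between R3 and R2 lay between 9.82e-05 and 0.0479.

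Over all genes, the largest rises from R2 to R3 also included Artn (6.54 ± 0.74), which encodes the neurotrophic factor artemin, the cathepsin gene Ctsf (6.51 ± 0.60), Fn3k (6.26 ± 0.93), Mmel1 (5.95 ± 0.76), Runx1t1 (5.91 ± 0.79), Igfbp1 (5.61 ± 1.08) and Prr15l (5.52 ± 0.46). The largest falls were in Tmem120a (-4.50 ± 0.89), Zfp61 (-4.25 ± 0.76), Zfp551 (-4.00 ± 0.85), Panx1 (-3.99 ± 0.65) and Msrb2 (-3.98 ± 1.07). Dkkl1, Tango6, Ppp2r3d, B9d1 and Dlg3 followed, with changes from -3.96 to -3.75. Each of these 10 fell below the array median in R3, and Artn, Ctsf, Mmel1, Igfbp1 and Prr15l lay below it in R2, so the sizes of these changes are less certain than their direction. The R3 arrays differed in Msrb2, with an SD of 2.57, and over arrays left out in turn its change ranged from -4.75 to -2.50. The limma adjusted p of these 17 genes lay between 0.000221 and 0.0277. With 1 array left out it lay between 0.056 and 0.0971 for Msrb2 and Tango6 without replicate 1 or 2 of R2, Tango6 without replicate 2 of R3, Ppp2r3d without replicate 1 or 2 of R2 or 2 or 3 of R3, and Zfp551 and Dlg3 without replicate 1 of R2.

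Markers of other liver cell types moved with the same step. All 14 measured hepatocyte markers rose, among them Ahsg (4.81 ± 1.05), Apoa1 (4.58 ± 0.46), Fgg (4.33 ± 0.56) and the albumin gene Alb (4.09 ± 0.44), and the median change was 3.82, or 3.96 relative to the median of all genes. Alb had log2 signals of 10.65 ± 0.37 (SD, n = 3) in R2 and 14.74 ± 0.40 (SD, n = 3) in R3, where it lay on average at percentile 99.4 of the array. Of 13 endothelial and stromal markers 6 rose, including Col3a1 (3.26 ± 0.71), Cxcl12 (2.36 ± 0.63) and Dcn (2.35 ± 0.47). Of 15 macrophage markers 1 rose, C1qc by 2.36 ± 0.61. None of the 13 granulocyte, 12 megakaryocyte, 10 lymphocyte or 7 mast cell markers was called, over all genes or adjusted over the list alone, with medians of -0.88, 0.23, -1.46 and 0.06 and camera adjusted p of 0.235, 0.367, 0.146 and 0.572, while under the replicate block 1 megakaryocyte marker was higher over all genes. Adjusted over the list alone, 14 hepatocyte, 9 endothelial and stromal and 1 macrophage marker rose. The camera adjusted p was 9.94e-13 for the hepatocyte, 0.00014 for the endothelial and 0.0817 for the macrophage list, and the adjusted p was 0.29 and 0.30 for the hepatocyte and endothelial lists with an estimated correlation. Cxcl12 and C1qc lost their calls without replicate 1 or 2 of R2 or of R3 (limma adjusted p from 0.0555 to 0.106), Ahsg without replicate 2 of R3 (0.0578) and Col3a1 without replicate 1 of R2 (0.0573). Ahsg, Col3a1, Cxcl12, Dcn and C1qc lay below the array median in R2. The pyruvate carboxylase 3' minus 5' difference was also higher in R3 (2.45 to 3.29) than in R2 (0.75 to 1.84). The other controls overlapped between these stages. In R2 and R3 the beta-actin difference was 0.32 to 0.79 and 0.24 to 0.83. That of Gapdh was -0.46 to -0.13 and -0.18 to -0.04, and that of the transferrin receptor 1.63 to 3.20 and 1.88 to 2.58.

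In all, 2716 genes were called between R3 and R2 (limma, adjusted p under 0.05), 1388 higher and 1328 lower in R3, and the arrays of the 2 stages did not overlap for 2693 of them. Over all genes the share without overlap was 49.9%, and chance gives 10%. The median change of all genes was -0.14, or 0.01 with each array centred on its median. The share higher was 51.1%, and 60.9% after median centring. With the replicate block 4197 genes were called, 2696 of them among the 2716, and the larger part, 2377, was lower in R3 and 1820 higher. The count was 840 without replicate 1 of R2, with 637 higher and 203 lower, and 1095 without replicate 2 of R2, and without replicate 1 or 2 of R3 it was 1515 or 845. Of 103 calls of genes covered by the rule for named genes, 32 and 23 passed the threshold no more without replicate 1 or 2 of R2, and 13 and 28 without replicate 1 or 2 of R3. Without replicate 3 of R2, replicate 3 of R3 or either R1 array, 8, 7 and 7 did.

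R5 was compared with R3 to ask what changes at the end of the series. The kinase gene Pask was the only gene called: log2 signal was 5.97 ± 0.13 (SD, n = 2) in R5 and 8.69 ± 0.11 (SD, n = 3) in R3, a fall by 2.73 ± 0.32 (limma adjusted p = 0.0467). Its R5 level was below the array median. The limma adjusted p of Pask lay between 0.0527 and 0.204 without the filter on dim probe sets, with default or robust eBayes, with array weights, in a fit of only these stages, and without any 1 array of R1, R2 or R3 or replicate 2 of R5. DNA replication genes were lower in R5 as a group. All 26 changes were negative, with a median of -1.50, or -1.70 relative to the median of all genes, 0 were called over all genes and 24 were lower adjusted over the list alone. Examples were Ccne2 (-2.45 ± 0.52), Cdc6 (-2.33 ± 0.38), Tyms (-2.18 ± 0.56) and Gins1 (-2.08 ± 0.44). With the replicate block 9 of the 26 were called, and the limma adjusted p of Ccne2, Cdc6 and Gins1 was 0.0403. The camera adjusted p of the list was 1.39e-22, against an adjusted p of 0.29 with an estimated correlation. Of 26 mitosis genes 24 changes were negative, with a median of -0.71 and 11 lower adjusted over the list alone, including Ndc80 (-1.48 ± 0.31) and Kif23 (-1.26 ± 0.26; limma adjusted p = 0.048 with the replicate block). Camera gave an adjusted p of 7.82e-09, and the adjusted p was 0.41 with an estimated correlation.

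**Figure D3:**
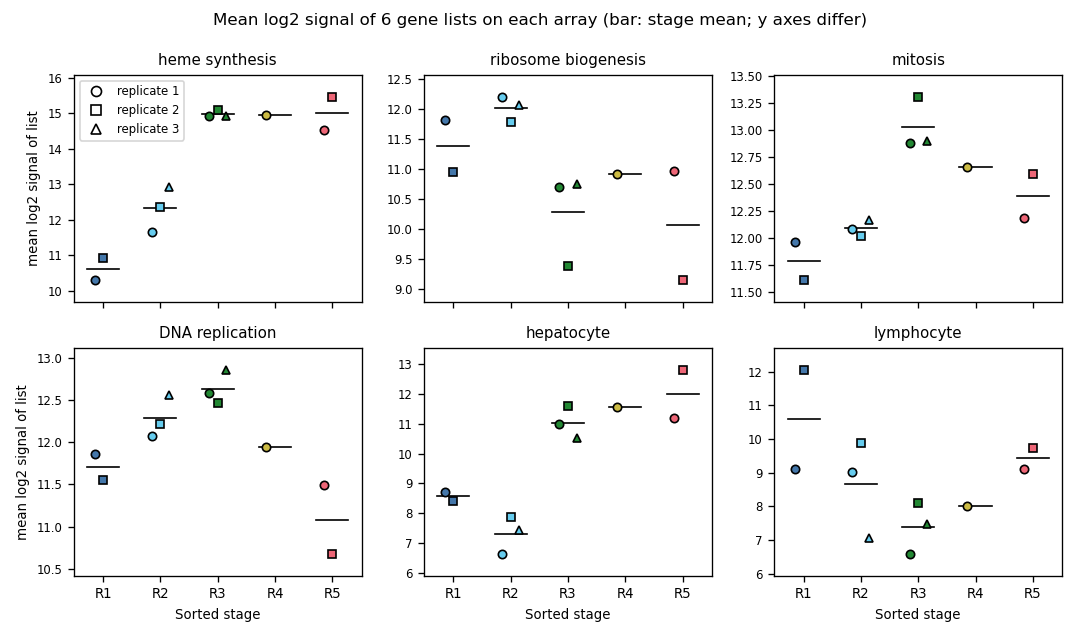
Mean log2 signal over the measured members of 6 gene lists on each of the 11 arrays by sorted stage, with symbols for the replicate number and a bar at the stage mean; the y axes differ. The DNA replication mean was 12.46 to 12.85 on the R3 arrays, 11.94 on the R4 array and 11.49 and 10.68 on the R5 arrays.

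In the ubiquitin list 16 of 19 changes from R3 to R5 were positive, 6 higher adjusted over the list alone, with values of 1.88 ± 0.57 for Ube2o, 1.72 ± 0.33 for Ube2b and 1.70 ± 0.48 for Ube2h. The camera adjusted p was 0.00382, against an adjusted p of 0.52 with an estimated correlation, and without replicate 2 of R5 the camera adjusted p was 0.73. With the replicate block the limma adjusted p of Ube2o, Ube2b and Ube2h lay between 0.0403 and 0.0441. Oxidative phosphorylation genes had a median of -0.44, with 23 of 26 changes negative, 0 called, or 1 lower under the replicate block, and 1 lower adjusted over the list alone (camera adjusted p = 6.99e-05; adjusted p = 0.52 with an estimated correlation). Of the genes named above, Hipk2 differed by 0.61 ± 0.40 and Tfrc by 0.19 ± 0.36 (limma adjusted p = 0.401 and 0.783). The Tfrc difference was -0.10 with each array centred on its median. Of 3 tested Tfrc probe sets 2 had the opposite sign, and of 7 Hipk2 probe sets 1 did. The lymphocyte, progenitor, endothelial, megakaryocyte and hepatocyte lists were higher in R5, with medians of 2.22, 1.29, 1.13, 1.07 and 0.93. With each array centred on its median these were smaller, at 1.93, 1.00, 0.84, 0.78 and 0.64. The camera adjusted p of these 5 lists lay between 0.000228 and 0.0248. With an estimated correlation their adjusted p lay between 0.46 and 0.56, and 0 of their members were called. Of the members, 2 megakaryocyte markers and 0 of the other 4 lists were higher adjusted over the list alone. Without replicate 1 of R5 the camera adjusted p was 0.165 for the progenitor, 0.327 for the megakaryocyte and 0.158 for the endothelial list. Without replicate 2 of R5 it was 0.0679 for the lymphocyte and 0.746 for the hepatocyte list, which then turned direction, and without replicate 3 of R3 it was 0.063 for the hepatocyte and 0.0538 for the megakaryocyte list.

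The single call between R5 and R3 stood beside 2488 genes with an unadjusted p under 0.05 in limma. The median change of all genes was 0.20, or -0.09 with each array centred on its median. With the replicate block 169 genes were called, 33 higher and 136 lower in R5, and with each array centred on its median 205 were called, 11 higher and 194 lower. With only the arrays numbered 1 and 2 and the block, a setting chosen after seeing the data, the balance turned: 644 were called, 373 higher and 271 lower. Without any 1 array of R2 or R3 the count was 0. Leaving out replicate 1 of R5 raised the count and leaving out replicate 2 lowered it, with 1 R5 array left in each case. The Gapdh 3' minus 5' difference was higher in R5 (0.23 and 0.20) than in R3 (-0.18 to -0.04), and that of pyruvate carboxylase was 4.62 and 2.27 in R5 against 2.45 to 3.29 in R3.

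R5 was compared with R1 to span the replicated series. Of 17 membrane genes 16 rose and of 7 heme genes 7 rose, with median changes of 4.78 and 3.87, and the counts adjusted over the list alone were also 16 and 7. The camera adjusted p was 4.03e-16 and 1.73e-08, and for both lists the adjusted p = 0.29 with an estimated correlation. The largest rises were in Fn3k (8.32 ± 1.14), Hbb-bh1 (7.58 ± 0.73), Hbb-b2 (7.57 ± 1.26), Mageb16 (7.49 ± 1.75) and Alas2 (7.45 ± 1.40), and the largest falls in Gpr160 (-4.95 ± 1.40), Hdac8 (-4.71 ± 1.36), Dnmbp (-4.53 ± 1.24), Atg16l2 (-4.42 ± 1.32) and Ccdc86 (-4.38 ± 1.26). Fn3k and Mageb16 were below the array median in R1, and the 5 that fell were below it in R5. The R1 arrays differed, with SDs of 3.19 in Fn3k, 3.13 in Hbb-b2, 4.02 in Mageb16 and 3.90 in Alas2. The changes of these 4 genes were 6.06, 5.36, 4.64 and 4.69 without replicate 1 of R1, so their size depends on that array. The limma adjusted p of Mageb16 was then 0.12, and without replicate 2 of R5 it was 0.138 for Mageb16 and 0.0541 for Alas2. Without replicate 1 or 2 of R1 or replicate 2 of R5 the limma adjusted p of the 5 genes that fell lay between 0.0871 and 0.248. With replicate 2 of R5 left out the change of Ccdc86 was -1.93, and with replicate 1 of R5 left out it was -6.82. The adjusted p in limma lay between 0.0513 and 0.0622 for all 5 without replicate 1 of R2, and in that range for some of them without replicate 2 of R2 or replicate 1 or 3 of R3, and it was 0.095 for Atg16l2 without replicate 1 of R5. Hipk2 rose by 3.38 ± 0.43, Tfrc by 3.19 ± 0.39 and 13 of 14 hepatocyte markers also rose, or 14 adjusted over the list alone (camera adjusted p = 4.35e-10; adjusted p = 0.29 with an estimated correlation). Of 13 endothelial and stromal markers 5 rose, and also 5 adjusted over the list alone, among them Cxcl12 (3.70 ± 0.78) and the lumican gene Lum (3.06 ± 0.57). The median of that list was 1.25, or 1.56 relative to the median of all genes (camera adjusted p = 0.0019; adjusted p = 0.41 with an estimated correlation). Both genes lay below the array median in R1, and Cxcl12 lost its call without replicate 1 of R1 or 2 of R5 (limma adjusted p = 0.0766 and 0.087). Of the other cell type lists, 1 megakaryocyte marker rose and 0 macrophage, granulocyte, lymphocyte or mast cell markers were called, over all genes or adjusted over the list alone (camera adjusted p from 0.285 to 0.611 for these 5 lists). The pyruvate carboxylase 3' minus 5' difference was 0.20 and 0.38 in R1 against 4.62 and 2.27 in R5, and that of Gapdh was -0.01 and -0.46 in R1 against 0.23 and 0.20 in R5. Hbb-b2, Dnmbp and Ccdc86 had another probe set of opposite sign. The limma adjusted p of these named genes lay between 0.000131 and 0.0437.

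Between R5 and R1 2195 genes were called (limma, adjusted p under 0.05), 1334 higher and 861 lower in R5, and their arrays did not overlap. Over all genes 64.7% did not overlap, and chance gives 33.3%. The share higher was 60.8%, and 70.8% after median centring, which moved the median change of all genes from -0.31 to -0.16. With the replicate block 3735 genes were called, and the majority turned, with 1714 higher and 2021 lower. It also turned without replicate 1 of R5, with 1559 higher and 2781 lower. Without replicate 1 or 2 of R1 the count was 752 or 952, and without replicate 1 or 2 of R5 it was 4340 or 631. Of 85 calls of genes covered by the rule for named genes, 33 and 25 passed the threshold no more without replicate 1 or 2 of R1, and 5 and 36 without replicate 1 or 2 of R5. Without replicate 1, 2 or 3 of R2, 10, 6 and 3 did, and without replicate 1, 2 or 3 of R3, 6, 1 and 6. Flvcr1, an iron-list gene, fell by 2.20 ± 0.52 (limma adjusted p = 0.0192), and with the mean of its probe sets the change was 0.02.

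R4 had 1 array, and its differences have no replicate check of their own. Tfrc was at 15.34 in R4, against 15.43 ± 0.18 (SD, n = 3) in R3 and 15.62 ± 0.72 (SD, n = 2) in R5, and Hipk2 was at 14.17, against 13.96 ± 0.54 in R3 and 14.57 ± 0.42 in R5. Across genes the R4 array correlated at 0.90 to 0.93 with the R3 arrays, 0.86 and 0.92 with the R5 arrays and 0.77 to 0.84 with those of R1 and R2. Assuming that the lone array varies like the others, limma called 0 genes between R4 and R3 and 0 between R5 and R4, where 461 and 441 had an unadjusted p under 0.05. With the replicate block and with default eBayes the counts were also 0. The median differences of all genes were 0.22 and -0.10, or -0.06 and -0.11 with each array centred on its median. Without replicate 1 of R5, 6 genes were called between R5 and R4.

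The authors' deposited table compares each stage with R2 over 45037 probe sets. It holds a p-value under 0.05 for 1163 probe sets in R3 against R2, of which 944 were higher and 219 lower in R3, and for 5129 probe sets in R5 against R2, of which 3913 were higher and 1216 lower in R5. For R1 against R2 and R4 against R2 the authors' deposited table holds 0 such probe sets, with smallest p-values of 0.143 and 0.0547.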

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

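The block with only the arrays numbered 1 and 2 was chosen after the result was seen. It gave 90 genes for R2 against R1, 4917 for R3 against R2, 644 for R5 against R3 and 4777 for R5 against R1. The replicate-number block on all arrays gave 0 genes for R2 against R1, 4197 for R3 against R2, 169 for R5 against R3 and 3735 for R5 against R1, and moved no other count of genes over all genes tested by over 1.5 times. Some counts within lists that it moved further are given beside those lists. Others are not printed, such as cell cycle brakes between R5 and R3, from 0 to 1 lower. For R2 against R1 (61 genes), default eBayes and a fit of only the stages compared gave 0, the mean of probe sets 36, all probe sets 1 (counted as probe sets), array weights 154 and an adjusted p under 0.01 gave 0. For R3 against R2 (2716) all probe sets gave 4450, array weights 4832 and the stricter p 691. For R5 against R3 (1), quantile normalization gave 14, median centring 205, no filter 0, the stricter filter 77, the floor 43, the mean of probe sets 7, and default eBayes, robust eBayes, only the stages compared, array weights and the stricter p gave 0. For R5 against R1 (2195) only the stages compared gave 700, all probe sets 3997, array weights 939 and the stricter p 690. For the F-test over stages (4839) all probe sets gave 7897 and the stricter p 1232. Counting probe sets tests more features and the stricter p admits fewer; for the others the cause was not tested. Leaving out 1 array gave 2695 to 6131 genes for the F-test, 0 to 87 for R2 against R1, 840 to 3920 for R3 against R2, 0 to 633 for R5 against R3, 631 to 4340 for R5 against R1 and 0 to 6 for R5 against R4. R4 against R3 stayed at 0 in every alternative run, and a fit of only the stages compared was not run for R4.

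Of the 104 list tests 59 passed, 0 did with an estimated correlation, 31 with fry and 54 to 62 with 1 array left out. Without replicate 2 of R5 the hepatocyte list turned direction between R5 and R3, with an adjusted p of 0.746 in a range from 7.70e-07 over arrays left out, and the cause was not tested. Under the block 59 of the 59 list calls were kept in direction and threshold. Of the calls of genes covered by the rule for named genes, Flvcr1 between R5 and R1 alone turned direction in the alternatives run, to 0.019 with the mean of its probe sets (limma adjusted p = 0.981), of which 1 of 2 has the opposite sign. Under the block 189 of them held and 30 passed the threshold no more, all 30 in R2 against R1. Of these calls, 56 were lost in a fit of only the stages compared (30 in R2 against R1 and 25 in R5 against R1) and 53 with default eBayes (30 in R2 against R1, 10 in R3 against R2 and 12 in R5 against R1). The mean of probe sets ended 41, array weights 25 (24 in R5 against R1), quantile normalization 20, median centring 9, no filter 9, the block on the arrays numbered 1 and 2 6, robust eBayes 5, the stricter filter 3 and the floor 1. With 1 array left out, from 6 to 68 of them were lost. No detection calls were used, so signal over background limits the sizes of changes in dim genes.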

Other observations

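The tests of array scaling, of other cell types, of the arrays numbered 2 and of the count between R5 and R3 were chosen after the result was seen, while the splits of the arrays and the correlation of hepatocyte markers were fixed before their values were known. Genes named here outside the rule for named genes were chosen after their values were seen.

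Some transcripts of granulocytes were abundant. S100a8 had mean log2 signals of 15.24, 14.94, 15.35, 15.45 and 16.34 from R1 to R5, and Mpo, a myeloperoxidase gene of granulocyte precursors, had means of 14.51, 14.64, 13.87, 14.65 and 13.64. Neither was called between consecutive replicated stages (limma adjusted p from 0.21 to 0.963). Ngp had means of 14.82 in R1, 12.59 in R2, 13.16 in R3 and 15.40 in R5, and Lyz2 had means of 14.48, 12.34, 12.37 and 14.45 in these stages, with limma adjusted p from 0.231 to 0.978. Replicate 3 of R2 stood apart, at 10.19 in Ngp, 10.16 in Lyz2 and 8.04 in Ltf, against 13.26 and 14.32, 12.94 and 13.93, and 10.66 and 12.68 on the other R2 arrays, so the R2 means of Ngp and Lyz2 depend on it. The cyclin gene Ccnd3 rose by 1.80 ± 0.27 (SE) from R2 to R3 (limma adjusted p = 0.00228) and differed by -1.64 ± 0.30 between R5 and R3 (limma adjusted p = 0.0525, or 0.048 with the replicate block). In both comparisons 1 of its 3 tested probe sets had the opposite sign.

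The R1 arrays differed in red cell genes. Replicate 2 exceeded replicate 1 by 5.51 in Alas2, 4.42 in Hbb-b2 and 3.88 in Slc4a1 on the log2 scale. In R2 replicate 1 was the lowest, at 8.18 in Alas2, 6.42 in Hbb-b2 and 9.23 in Slc4a1, against 11.10, 9.67 and 12.67 on replicate 2 and 10.77, 8.43 and 13.13 on replicate 3.

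Between R3 and R2, 2716 genes were called with the real stages and at most 0 with the other splits of the 6 arrays into 3 and 3. With 10 splits in all, of which 1 reached the real count, a share under 0.05 cannot be had. Every other split also puts arrays of both stages in 1 group, so the stage difference widens the spread. Few calls can then be had, and no conclusion is drawn from the contrast.

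Hepatocyte markers were higher in R3 than in R2 in 14 of 14 genes. With each array centred the median change was 3.97 (SD of members 0.72, over genes of the same arrays). Centring could move it little, since the median change of all genes was -0.14. It is that small shift of all genes that argues against array scaling as the whole explanation. A lower share of erythroid RNA that raises all other cell types alike is also argued against. The hepatocyte median lay 2.10 above the highest other median, 1.72 for endothelial and stromal markers (SD of members 1.21). The other 5 medians ran from 0.50 for macrophage to -1.46 for lymphocyte markers. The endothelial list mean was 5.03 to 5.48 on the R2 arrays, below the array medians of 5.74 to 6.06. The size of that list's rise is therefore less certain. The granulocyte list was not dim in R2 (11.32 to 13.60), and its median was -0.88. RNA of hepatocytes as 1 shared source remains a candidate explanation. Over 10 arrays the deviations of the 14 markers from stage means had a median pairwise correlation of 0.70. The 2 deviations of R1 are mirror images, as are the 2 of R5, so the 10 values are not independent and hold 6 degrees of freedom. The correlation was above that of 99.1% of 1000 random lists of genes that rose to a like extent, computed in the same way. These lists were not matched on signal level. The list mean was highest on the array numbered 2 in R2, R3 and R5 (7.88, 11.58 and 12.79), though not in R1 (8.42 against 8.71). The correlation therefore cannot tell 1 source from variation shared by replicate number. Afp and Alb lay on average at percentiles 99.6 and 99.4 of the R3 arrays, and none of the 14 markers is in another list. Ter119 is an antigen of erythroid cells, but the share of hepatocytes left in the sorted fractions was not measured here. Expression of these genes in erythroid cells was not tested.

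Embryonic globin transcripts were lower on the arrays numbered 2 of R3 and R5 than on the others of their stage, with a mean difference of -2.36 (SD 1.45 over 6 differences) in Hba-x, Hbb-y and Hbb-bh1. Less mature cells on those arrays would lower other red cell genes too, while Hbb-b2, Alas2 and Slc4a1 differed by 0.60 in the other direction (SD 0.45). That SD is over 3 genes on 1 array numbered 2 of each stage. In R3 the differences were 1.18 for Hbb-b2, 0.27 for Alas2 and -0.08 for Slc4a1. With so few arrays less mature cells cannot be excluded. A lower level through the whole set numbered 2 stays open: on the arrays numbered 2 of R1 and R2 the same embryonic genes were higher by 1.62 (SD 0.80), but Hbb-b2, Alas2 and Slc4a1 were higher by 3.20 (SD 1.65). Relative to those genes the embryonic ones differed by -1.58 (SD 1.46), so the measured and the relative difference go opposite ways. No other biological explanation was tested.

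A single gene was called between R5 and R3. Whether variation that arrays share by replicate number hides changes cannot be told. The block raised the count to 169, but from only 1 gene. Without the block the stricter filter gave 77 and the floor 43, and in R2 against R1 the block lowered the count from 61 to 0. Whether a shift of whole arrays within a stage hides changes stays open, since median centring gave 205 genes and quantile normalization 14. Without any 1 array of R2 or R3 the count was 0. Leaving out replicate 1 of R5 raised the count and leaving out replicate 2 lowered it. In each case 1 R5 array is left, and the difference between the R5 arrays no longer enters the spread. The simulated fit recovered 80.3% of genes changed by 4 on the log2 scale and 23.9% of those changed by 2 in this comparison. Its noise was independent between genes and arrays and few genes were changed, so these shares do not give the power on the real arrays.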
